A study of Mus musculus with 8 samples.

How the data were processed

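Gene expression was measured in NG4 mouse embryonic stem cells 48 h after reverse transfection with siRNA. Per the labels' protocols, 5 ng of total RNA was amplified with the Ovation V2 system and the biotin-labelled cDNA was hybridised to Affymetrix arrays. The deposited intensity values had been computed with RMA per the submitters' processing notes, with no version given. RMA in its usual form corrects the background, sets all arrays to the same distribution and summarises probes into a probe set. Its settings here are not given in the sources used here. A method that equalises the arrays' distributions hides any change in total RNA per cell, so fold changes are relative to the bulk of probe sets. The values were on a linear scale, and log2 was taken before any test. No scanner files were used here, so background and detection calls could not be recomputed.

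The table held 45101 probe sets. The 64 control probe sets were left out, which left 45037. GEO's platform annotation gave 34945 of them 1 gene symbol, 932 several and 9160 none. Symbols of 34741 probe sets were looked up through their Entrez identifiers in the reference gene table, and 0 were renamed. A gene was named only from a probe set with 1 symbol, and it was represented by its probe set with the highest mean log2 value over all 8 arrays, which gave 18193 genes. For the genes named, no other probe set of the gene passed the threshold in the opposite direction.

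Samples were grouped by their titles into siNonTarget, siSox2, siPsmd14 and siDdb1, with 2 arrays in each. Each knockdown was compared with siNonTarget, and the knockdowns were compared with each other. The 8 arrays entered 1 linear model in limma 3.58.1 under R 4.3.3 (lmFit and eBayes without trend), so that the groups shared an estimate of the spread. P-values were adjusted by the Benjamini-Hochberg method over the 45037 probe sets, and the threshold was an adjusted p of 0.05. The prior held 5.02 degrees of freedom and the total was 9.02. The number of arrays limits the precision. The replicate number was not a block. Every adjusted p of a gene below comes from this limma model.

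For the description of gene groups, 22 gene lists were fixed before the data were examined. They covered naive, general and primed pluripotency, trophectoderm, primitive endoderm, mesoderm and mesendoderm, neuroectoderm, proteasome subunits, heat shock chaperones, the unfolded protein and integrated stress response, p53 targets, the NRF2 oxidative stress response, CUL4-DDB1 ligase components, DNA replication, mitosis, the interferon response, fibroblast markers, the 2-cell-like state, the germline, cholesterol synthesis, extracellular matrix and adhesion, and signalling feedback targets. The targeted genes were left out of the lists. Lists were tested with limma's camera with a preset correlation of 0.01 between genes, adjusted over the 22 lists within each comparison. Estimating the correlation for each list and fry were alternatives, and no camera call held with an estimated correlation in any comparison. Fry tests whether a list's genes move, on balance, in 1 direction, and does not compare them with other genes.

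Named genes followed a rule fixed at the same time. Sox2, Psmd14, Ddb1, Pou5f1 and Nanog were always named. Per knockdown the 6 largest rises and 6 largest falls past the threshold were named if both knockdown arrays lay on the same side of both control arrays. Up to 4 members past the threshold with the smallest p were named from each list, or 2 where none passed. In a direct comparison the 5 largest differences each way were named, with members of lists that passed. Where nothing passed, the 5 genes with the smallest p were named as not having passed. The groups, the tests and the alternatives were also chosen before the data were examined. The alternatives were leaving out the dimmer 50% of probe sets or those with a mean log2 value under 5, subtracting array medians, quantile normalization, eBayes with trend and robust, array weights, the 4 arrays compared alone, the replicate block, 1 probe set per gene, an adjusted p of 0.01, a 2-fold minimum and leaving out each array. A block with the siDdb1 numbers crossed was added after the data were seen.

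Comparisons that share control arrays were set against 100 simulations of unchanged groups. The scripts were tested on simulated data of 45037 probe sets with 100 genes changed by 1 log2 unit and 100 by 2. At 1 log2 unit 92% were recovered for siSox2, 97% for siPsmd14 and 94% for siDdb1. At 2 log2 units 100% were recovered for each. False calls numbered 15, 13 and 15, and unshifted lists called numbered 1, 0 and 1. The simulated noise was independent between probe sets, and the same gene changes were planted in each knockdown. These rates therefore check the scripts and need not hold for the measured arrays, where genes of a list are correlated. The simulated lists were tested with the preset correlation only. Whether an estimated correlation can recover a planted list shift with 2 arrays per group was not tested. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. The 12 genes drawn per array were picked from the named genes after their values were seen.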

Results

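Mouse embryonic stem cells of the line NG4 received small interfering RNAs (siRNAs) against Sox2, Psmd14 or Ddb1, or a non-targeting siRNA, and their RNA was profiled 48 h later on Affymetrix expression arrays. The labels give 8 arrays in 4 groups, with 2 arrays in each group. Sox2 is a transcription factor of the pluripotency network. Psmd14 is the deubiquitinase of the proteasome's regulatory particle, and Ddb1 is the adaptor of the CUL4 ubiquitin ligases. The series title places the experiment in a study of the ubiquitin-proteasome system in self-renewal. The non-targeting group, siNonTarget, was the control of each knockdown. The array medians lay between 27.37 and 28.84 intensity units, and the median SD between the 2 arrays of a group was 0.102 to 0.12 on the log2 scale. The first principal component held 32.5% of the variance and set the siSox2 arrays (34.95 and 59.23) apart from the other 6 (-26.3 to -2.27). On the second component, with 25.4%, siPsmd14 replicate 1 lay at -55.8 and replicate 2 at -21.5. The number of arrays limits the precision. The median SE of a log2 fold change was 0.151, which is 0.342 on either side at 95% for a single probe set. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these arrays, which may be technical.

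The targeted transcripts were read first. Ddb1 signal in siDdb1 was 22.1% of the control mean on replicate 1 and 46.1% on replicate 2, a log2 fold change of -1.65 (SE 0.28, n = 2 arrays per group). In the limma test this change had an adjusted p of 0.147 against siNonTarget and did not pass the threshold. Ddb1 was lower in siDdb1 than in siSox2 (-1.92, adjusted p = 0.00888), and it was higher in siPsmd14 than in siDdb1 (1.87, adjusted p = 0.0321). Without siDdb1 replicate 2 the change against siNonTarget was -2.18 with a limma adjusted p of 0.00934. Sox2 signal in siSox2 was 83.9% and 70.0% of the control mean (log2 fold change -0.38, SE 0.16, adjusted p = 0.301). Psmd14 signal in siPsmd14 was 90.6% and 82.8% (-0.21, SE 0.13, adjusted p = 0.522). Neither difference passed the threshold, and both lay in the direction the labels imply. The Sox2 value of siPsmd14 replicate 1, at 12.07, lay below that of siSox2 replicate 1, at 12.10. Each target was read by a single probe set. Pou5f1 and Nanog, core pluripotency factors, passed the threshold in none of the 3 knockdowns. Their log2 fold changes were -0.34 and -0.40 in siSox2, -0.12 and -0.45 in siPsmd14, and -0.14 and -0.23 in siDdb1.

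**Figure D1:**
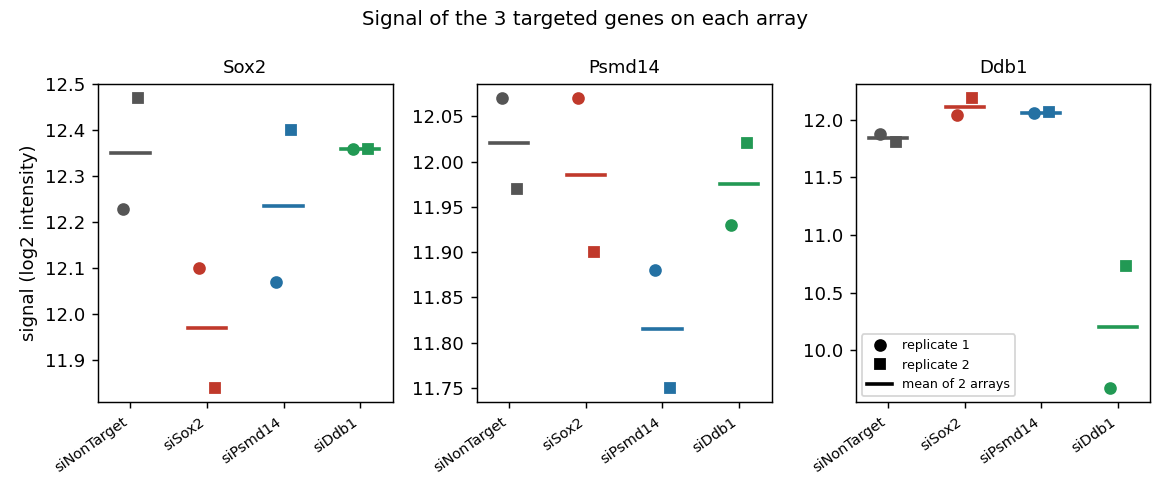
Signal of Sox2, Psmd14 and Ddb1 in log2 intensity on each of the 8 arrays, by group. Circles are replicate 1, squares replicate 2 and bars the mean of 2 arrays. Ddb1 lay at 9.67 and 10.73 in siDdb1 and at 11.81 or above elsewhere, while the Sox2 and Psmd14 axes span under 1 log2 unit.

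In siSox2, genes of the trophoblast lineage rose and several naive pluripotency genes fell. The 6 genes with the largest rises were Plac1, a placenta-enriched gene (log2 fold change 6.23, SE 0.21, 75.1-fold), the epithelial keratin Krt7 (4.47), the actin-bundling Lcp1 (4.05), the kinase gene Nrk (3.89), the homeobox gene Irx3 (3.84) and the growth factor Igf2 (3.78). The 6 with the largest falls were the trypsin inhibitor Spink1 (-3.16), the laminin chain Lama1 (-2.94), the peptidase Dpp4 (-2.52), the co-receptor Nrp2 (-2.43), the Wnt deacylase Notum (-2.33) and Kbtbd11 (-2.25). Of 26 measured trophectoderm genes, 17 rose and none fell over all probe sets, and 20 rose adjusted over the list alone. The members with the smallest p were Plac1, Krt7, the trophoblast regulator Ascl2 (3.50) and Cdx2, which directs trophectoderm fate (1.65, SE 0.13). The list's median was 1.5, and camera gave an adjusted p of 1.75e-23 with a preset correlation of 0.01. The list's call was lost under the other correlation setting (adjusted p = 0.312 with an estimated correlation), and fry gave an adjusted p of 0.0102.

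Of 21 measured naive pluripotency genes, 6 fell and none rose in siSox2 over all probe sets, and 12 fell adjusted over the list alone. They included the lysosomal mannosidase Manba (-1.97), the junction protein gene Jam2 (-1.69), the nuclear receptor gene Nr0b1 (-1.67) and the homeobox gene Gbx2 (-1.81). The median was -0.52 and camera gave an adjusted p of 1.23e-07 (adjusted p = 0.492 with an estimated correlation, 0.032 by fry). Of 20 general pluripotency genes none passed over all probe sets or adjusted over the list alone, and the list shifted down as a whole (median -0.22, camera adjusted p = 0.0179, adjusted p = 0.617 with an estimated correlation). Among 23 neuroectoderm genes 3 fell, namely Neurod1 (-2.22), Tubb3 (-0.88) and Pax6 (-2.17), and 5 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.0226, adjusted p = 0.51 with an estimated correlation). The primed pluripotency list did not pass (camera adjusted p = 0.0535), while Cdh2 (-1.17), Otx2 (-1.73) and Fgf15 (-1.74) fell, and 5 of 15 fell and 2 rose adjusted over the list alone. Of 26 fibroblast markers, which feeder cells would carry, 4 rose, among them Lgals1 (2.02), Tagln (1.87) and Col5a2 (1.73), and Thy1 fell (-1.06). Adjusted over the list alone, 6 rose and 4 fell (camera adjusted p = 0.0164, adjusted p = 0.51 with an estimated correlation). Col5a2 was higher by 1.1 without siSox2 replicate 2. The fibroblast collagens Col1a1 and Col3a1 lay at 4.01 and 3.39 on the log2 scale in siSox2 and at 3.65 and 3.28 in siNonTarget. The camera adjusted p without siNonTarget replicate 2 was 0.204 for the general pluripotency list, 0.187 for neuroectoderm and 0.0544 for the fibroblast markers, and without siSox2 replicate 2 it was 0.0504 for general pluripotency and 0.0881 for the fibroblast markers.

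Over all 45037 probe sets, 1320 passed an adjusted p of 0.05 in siSox2, with 847 higher and 473 lower, and 762 of them differed at least 2-fold. By their representative probe set, 778 of 18193 genes passed, 512 higher and 266 lower. In this limma test the count was 354 without siNonTarget replicate 1, 153 without siNonTarget replicate 2 and 304 without siSox2 replicate 2. Of the 48 called genes that the naming rule gives for siSox2, not all printed here, 28, 21 and 28 stayed past the threshold without those arrays, and the number of lists past the threshold went from 11 to 7 without siNonTarget replicate 2.

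In siPsmd14, rises outnumbered falls (82.3% of 609 calls, and 60.9% of 1295 without siPsmd14 replicate 2), and genes of several stress responses were among them. The 6 genes with the largest rises were Fosl1, a subunit of the AP-1 transcription factor (log2 fold change 4.59, SE 0.23, 24.1-fold), Apol8 (3.75), the necroptosis effector Mlkl (3.26), the dermokine gene Dmkn (3.12), the actin-severing gelsolin gene Gsn (2.83) and the integrin gene Itga8 (2.71). The largest falls were the receptor subunit gene Gabbr1 (-1.22), Tsix, the antisense partner of Xist (-1.16), Hpdl (-1.11), Cnpy1 (-1.07), the myelin gene Mobp (-1.05) and Gdap10 (-0.99). Of 35 measured p53 targets 6 rose and none fell over all probe sets, and 19 rose adjusted over the list alone. They included Mdm2, the ligase that degrades p53 (1.63, SE 0.15, 3.09-fold), Ddit4l (1.99), the kinase gene Plk2 (1.92) and the desmosomal Perp (4.01-fold). The list's median was 0.61 and camera gave an adjusted p of 1e-12 (adjusted p = 0.31 with an estimated correlation, 0.0648 by fry). Of 21 genes of the NRF2 oxidative stress response 4 rose, namely the malic enzyme gene Me1 (1.81), the autophagy receptor Sqstm1 (1.75), the catalase gene Cat (0.88) and the sulfiredoxin gene Srxn1 (1.61), and 5 rose adjusted over the list alone (camera adjusted p = 2.22e-05, adjusted p = 0.31 with an estimated correlation).

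Of 40 measured proteasome genes in siPsmd14, which leave out Psmd14 itself, none passed over all probe sets, while 13 rose and 1 fell adjusted over the list alone. The median was 0.28, with 33 members above 0 and 7 below. Psmd1 (0.60, adjusted p = 0.0649) and Psmd3 (0.53, adjusted p = 0.0982) had the smallest p among all limma tests of the list. Camera gave an adjusted p of 2.22e-05 for the list (adjusted p = 0.415 with an estimated correlation), and 0.0748 without siPsmd14 replicate 1. Of 23 heat shock chaperones 3 rose, the small heat shock protein genes Cryab (2.55) and Hspb8 (1.77) and the co-chaperone Bag3 (1.26), and 7 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.0183, adjusted p = 0.31 with an estimated correlation, and 0.186 without siPsmd14 replicate 2). Without siPsmd14 replicate 1 the fold changes were 2.13 for Cryab, 1.16 for Hspb8 and 0.985 for Bag3. The Actb 3' to 5' probe difference, a sign of RNA integrity, was 0.346 log2 on siPsmd14 replicate 1 and 0.0962 to 0.214 on the other 7 arrays. The 18S ribosomal RNA probe set read 13.09 on siPsmd14 replicate 2, 12.71 on siDdb1 replicate 2 and 10.68 to 11.7 elsewhere.

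The keratins Krt8 (2.63), Krt18 (2.37), Krt7 (1.94) and Krt19 (1.77) were the 4 trophectoderm genes that rose in siPsmd14, and 11 of 26 rose adjusted over the list alone. These keratins are expressed in simple epithelia in general. The list's median was 0.32 (camera adjusted p = 2.81e-05, adjusted p = 0.312 with an estimated correlation). Of 21 naive pluripotency genes none passed over all probe sets and 11 fell adjusted over the list alone, with a median of -0.55 (camera adjusted p = 3.88e-07, adjusted p = 0.31 with an estimated correlation). Fgf4 (-0.89) and Esrrb (-0.48) had the smallest p. General pluripotency genes shifted down with a median of -0.32 (camera adjusted p = 3.07e-05, adjusted p = 0.312 with an estimated correlation), and no member passed by either adjustment. The array medians of that list were -0.452 on siPsmd14 replicate 1 and -0.159 on replicate 2. The lists of DNA replication (median -0.16, camera adjusted p = 0.0111, adjusted p = 0.362 with an estimated correlation) and mitosis (median -0.19, camera adjusted p = 0.0107, adjusted p = 0.31 with an estimated correlation) shifted down, with no member past either adjustment. On siPsmd14 replicates 1 and 2 these lists had medians of -0.192 and -0.065 for DNA replication and -0.197 and -0.077 for mitosis. Without siPsmd14 replicate 1 their camera adjusted p was 0.0789 and 0.071, and for DNA replication it was 0.076 without siNonTarget replicate 1. Of 26 fibroblast markers S100a4 (1.18) and Tagln (1.66) rose, and 5 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.00257, adjusted p = 0.31 with an estimated correlation).

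In siPsmd14, 609 probe sets passed the threshold, 501 higher and 108 lower, and 395 differed at least 2-fold. By their representative probe set 343 genes passed, 309 higher and 34 lower. The limma count was 23 without siNonTarget replicate 1, 17 without siNonTarget replicate 2, 67 without siPsmd14 replicate 1 and 1295 without siPsmd14 replicate 2. Of the 38 called genes that the naming rule gives for siPsmd14, not all printed here, 3, 1, 5 and 32 stayed past the threshold without those arrays.

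**Figure D2:**
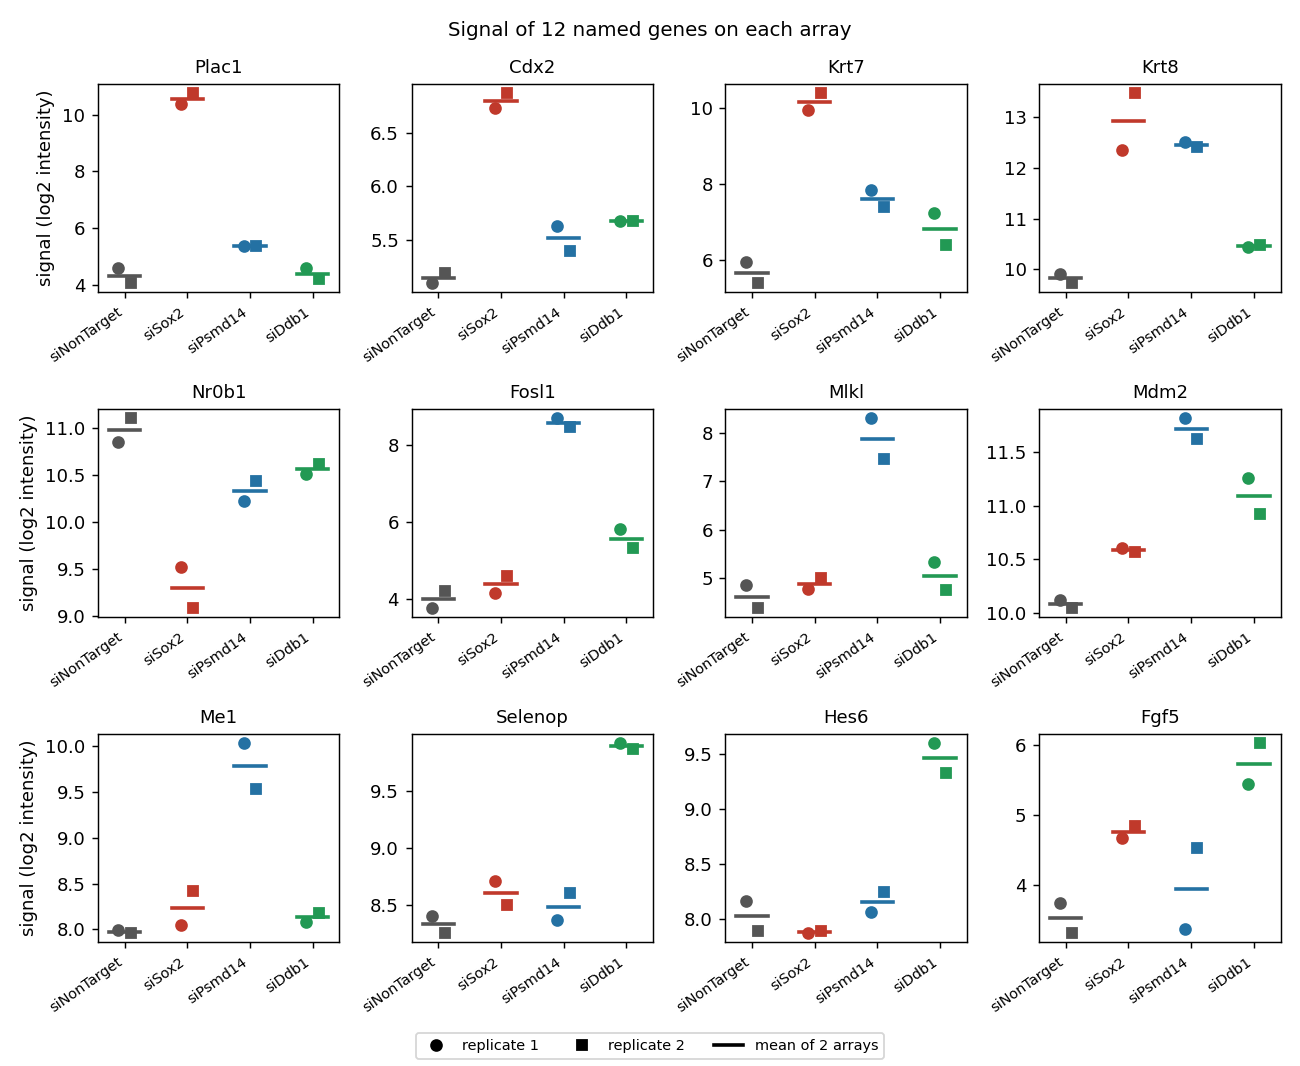
Signal in log2 intensity of 12 named genes on each array, by group, with circles for replicate 1, squares for replicate 2 and bars for the mean of 2 arrays. Plac1 read 10.36 and 10.76 in siSox2 against 4.08 to 5.37 elsewhere, Fosl1 read 8.69 and 8.46 in siPsmd14 against 3.76 to 5.8, and Hes6 read 9.6 and 9.33 in siDdb1 against 7.87 to 8.24.

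In siDdb1, 12 probe sets rose and none fell, and 8 genes passed by their representative probe set. The 6 with the largest rises were the casein gene Csn3 (log2 fold change 1.83, SE 0.22, 3.56-fold), the GDNF receptor gene Gfra1 (1.66), the selenoprotein gene Selenop (1.55), the insulin receptor substrate gene Irs4 (2.83-fold), the neurogenic regulator Hes6 (1.44) and Ndnf (1.35). Their limma adjusted p lay between 0.0448 and 0.049. Other probe sets gave 0.04 for Csn3, 0.36 and 0.51 for Gfra1, -0.29 for Irs4 and 0.01 for Ndnf, none past the threshold. Those probe sets had means of 2.712 to 3.775 in siNonTarget, below the medians of those arrays (4.788 and 4.833). Another probe set of Hes6 passed (1.30, limma adjusted p = 0.0448). Serinc5 (1.25) and Hoxd13 (1.22), which also rose, were named after their values were seen. The 5 genes with the smallest p on the lower side did not pass, namely Mobp (-1.30, adjusted p = 0.0529), Gabbr1 (-1.12, adjusted p = 0.0814), Ttc9b (-0.93), Itpka (-1.09) and Eif4g3 (-0.82). At an unadjusted limma p of 0.05, 3619 probe sets passed, against 2252 given by chance. Leaving out a siSox2 or siPsmd14 array left the fold changes of siDdb1 as they were (Csn3 1.83, Hes6 1.44). It left fewer arrays to estimate the spread, so a lower count there does not show dependence on that array. The adjusted count was 146 without siDdb1 replicate 2 and 0 without any other single array of the 8, and it was 0 with only the 4 arrays of this comparison in the fit or with the dimmer 50% of probe sets left out.

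No p53 target passed over all probe sets in siDdb1, and 20 of 35 rose adjusted over the list alone. The list's median was 0.61, the same to 2 digits as in siPsmd14, and camera gave an adjusted p of 2.84e-17 (adjusted p = 0.487 with an estimated correlation, 0.243 by fry). Mdm2 (1.01, SE 0.15, adjusted p = 0.0936) and the immune co-stimulator gene Cd80 (1.41, adjusted p = 0.147) had the smallest p in the limma test. Naive pluripotency genes had a median of -0.46, with 8 of 21 lower and 1 higher adjusted over the list alone (camera adjusted p = 7e-09, adjusted p = 0.487 with an estimated correlation). The primed pluripotency list, which in siSox2 had a negative median, shifted up in siDdb1 with a median of 0.50, and 5 of 15 rose adjusted over the list alone (camera adjusted p = 3.02e-07, adjusted p = 0.582 with an estimated correlation). Its leading members were the growth factor gene Fgf5 (2.21, adjusted p = 0.113) and the ERK phosphatase gene Dusp6 (1.11, adjusted p = 0.115). Fgf5 read 3.74 and 3.31 in siNonTarget, below the medians of those arrays (4.788 and 4.833). It read 4.67 and 4.84 in siSox2 and 5.44 and 6.02 in siDdb1. Another probe set of Fgf5 gave 0.11 in siDdb1 (limma adjusted p = 0.887). The trophectoderm list (camera adjusted p = 0.0508), the proteasome list (median -0.04, camera adjusted p = 0.253) and the fibroblast list (camera adjusted p = 0.0999) did not pass.

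**Figure D3:**
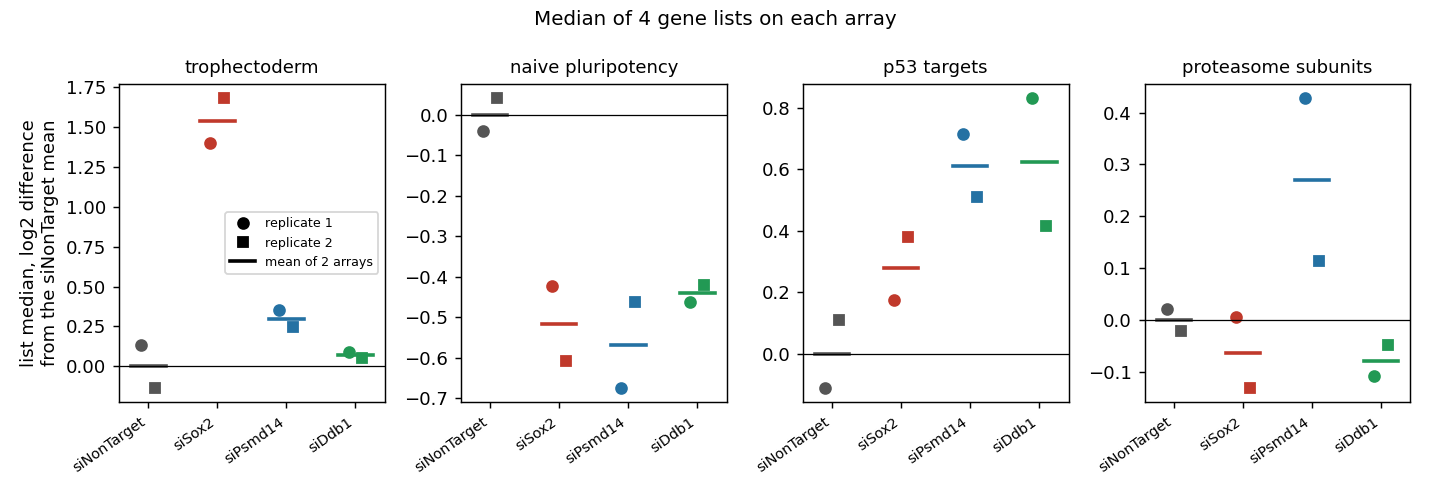
Median of the log2 differences from the siNonTarget mean over the members of 4 lists on each array, with circles for replicate 1, squares for replicate 2 and bars for the mean of 2 arrays. The proteasome list lay at 0.428 and 0.114 on the siPsmd14 arrays and between -0.131 and 0.021 on the others, and the naive pluripotency list lay between -0.675 and -0.421 on all 6 knockdown arrays. A high naive signal on the 2 shared siNonTarget arrays would lower all 6 values, which was not tested. The naive list passed by camera in no direct comparison (adjusted p = 0.118 for siPsmd14 and 0.131 for siDdb1 against siSox2, 0.723 for siPsmd14 against siDdb1).

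Set against siSox2 directly, 12 of 26 trophectoderm genes were lower in siPsmd14, and the p53, NRF2 and proteasome lists shifted up by camera with 3 of 35, 3 of 21 and 1 of 40 members past the threshold, though none of these lists passed with an estimated correlation. Plac1 (-5.20), Lcp1 (-4.14), Crxos (-3.70), Irx3 (-3.32) and Ascl2 (-3.15) were the 5 largest differences downward, and Fosl1 (4.20), Apol8 (3.81), the receptor kinase gene Tek (3.15), Fetub (3.15) and Fbxo2 (3.02) the 5 upward. Adjusted over the list alone, 17 trophectoderm genes were lower and 1 higher (camera adjusted p = 5.91e-14, adjusted p = 0.499 with an estimated correlation). Mdm2 (1.12), Ak1 (1.06) and Ddit4l (1.88) were the 3 p53 targets that were higher, and 6 were adjusted over the list alone (camera adjusted p = 0.00019, adjusted p = 0.571 with an estimated correlation). The proteasome list had a median of 0.32 with Psme4 (0.61) past the threshold and 7 higher adjusted over the list alone (camera adjusted p = 1.66e-06, adjusted p = 0.571 with an estimated correlation). Among 21 NRF2 genes Me1 (1.54), Gclm (0.65) and Srxn1 (1.36) were higher, and 8 were adjusted over the list alone (camera adjusted p = 0.000803, adjusted p = 0.499 with an estimated correlation). The naive pluripotency list did not pass (camera adjusted p = 0.118), with Nr0b1 (1.02), Gbx2 (1.16), Jam2 (1.33) and Manba (1.31) higher and Tfcp2l1 (-1.02) lower. These members lay outside the naming rule for direct comparisons and were named after their values were seen. Of the 22 lists 8 passed by camera and none with an estimated correlation. In all 1255 probe sets differed, 607 higher and 648 lower in siPsmd14. The limma count was 745 without either siNonTarget array, 325 without siSox2 replicate 2 and 395 without siPsmd14 replicate 1. The balance was near even and depended on single arrays, with 48.4% of the calls higher with all 8, 35.6% without siSox2 replicate 1, 53.2% without siSox2 replicate 2, 54.2% without siPsmd14 replicate 1, 50.7% without siPsmd14 replicate 2 and 51.1% without either siDdb1 array.

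Against siSox2, 16 of 26 trophectoderm genes were lower in siDdb1, and the primed and neuroectoderm lists shifted up by camera with 5 of 15 and 3 of 23 members past the threshold, though neither list passed with an estimated correlation. Neurod1 (3.47), Tek (3.45), Dpp4 (3.13), Spink1 (3.12) and Apol8 (2.95) were the 5 largest differences upward, and Plac1 (-6.16), Lcp1 (-4.62), Irx3 (-3.69), the choline dehydrogenase gene Chdh (-3.62) and Igf2 (-3.42) the 5 downward. Of the trophectoderm genes Eomes was higher (1.04), and 21 were lower and 1 higher adjusted over the list alone (camera adjusted p = 4.59e-19, adjusted p = 0.444 with an estimated correlation). Of 15 primed pluripotency genes Cdh2 (1.68), Dusp6 (1.44), Otx2 (2.10), Lef1 (1.28) and Fgf15 (1.87) were higher, and 11 were adjusted over the list alone (camera adjusted p = 1.91e-08, adjusted p = 0.534 with an estimated correlation). Neurod1, Fabp7 (0.76) and Meis1 (0.87) were the 3 of 23 neuroectoderm genes that were higher, and 6 were higher and 1 lower adjusted over the list alone (camera adjusted p = 0.000488, adjusted p = 0.534 with an estimated correlation, 0.026 by fry). Of the p53 targets Cd80 (1.45) and Ddit4l (1.49) were higher, and 4 were adjusted over the list alone (camera adjusted p = 0.00036, adjusted p = 0.723 with an estimated correlation, and 0.169 without siDdb1 replicate 1). Here too 8 lists passed by camera and none with an estimated correlation. In all 1387 probe sets differed, 619 higher and 768 lower in siDdb1. The limma count was 913 without either siNonTarget array, 321 without siSox2 replicate 2, 319 without siDdb1 replicate 1 and 854 without siDdb1 replicate 2. Of the calls 44.6% were higher with all arrays, 34.4% without siSox2 replicate 1 and 50.5% without siDdb1 replicate 2.

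The ubiquitin-proteasome knockdowns were also set against each other. In siPsmd14, Fosl1 (3.01), the biliverdin reductase gene Blvrb (2.95), Mlkl (2.85), Fbxo2 (2.66) and Snhg11 (2.63) were the 5 genes most above siDdb1. The interferon-inducible Irgm1 (-2.33), Gfra1 (-2.18), Cass4 (-1.87), Irs4 (-1.59) and the iron exporter gene Slc40a1 (-1.51) were the 5 most below. The proteasome list was higher in siPsmd14 (median 0.31, 35 of 40 members above 0, 4 higher adjusted over the list alone, camera adjusted p = 1.81e-08, adjusted p = 0.511 with an estimated correlation). The primed pluripotency list was lower in siPsmd14, with Dusp6 (-1.12) past the threshold and 9 of 15 lower adjusted over the list alone (camera adjusted p = 1.55e-06, adjusted p = 0.511 with an estimated correlation). Against the siNonTarget mean its median lay at -0.469 on siPsmd14 replicate 1 but at 0.321 on replicate 2, within the siDdb1 arrays (0.296 and 0.546), and the camera adjusted p was 0.000894 without siPsmd14 replicate 1. Among NRF2 genes Me1 (1.65) and Sqstm1 (1.47) were higher, and 6 of 21 were adjusted over the list alone (camera adjusted p = 3.73e-06, adjusted p = 0.511 with an estimated correlation). The p53 list did not differ past the threshold (median 0.10, quartiles -0.17 and 0.21, camera adjusted p = 0.618). By camera 11 lists passed, and none did with an estimated correlation. In all 186 probe sets differed, 146 higher and 40 lower in siPsmd14. The limma count was 41 without either siNonTarget array, 11 without siPsmd14 replicate 1, 884 without siPsmd14 replicate 2, 28 without siDdb1 replicate 1 and 70 without siDdb1 replicate 2. The share higher in siPsmd14, 78.5% with all arrays, was 55.5% without siPsmd14 replicate 2 and 55.7% without siDdb1 replicate 2.

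Genes called in both siSox2 and siPsmd14 numbered 94, of which 77 rose in both, 15 fell in both and 2 went opposite ways, namely Fetub (-0.70 and 2.45) and Zswim4 (-0.83 and 0.61). Krt8, Krt7, Col4a2, Cryab, Cdkn1a, Jun and Anxa2 were among those that rose, and Bmp4, Fgf17 and Tsix among those that fell; Jun, Anxa2, Fgf17, Fetub, Zswim4 and the genes called in both comparisons of a pair named next were chosen after their values were seen. Independent lists of these sizes would share 8.7 rises and 0.497 falls. Unchanged groups simulated against the same control arrays shared a median of 0 genes. With no gene changed, few are called in either comparison. This count therefore cannot show how far shared controls raise the overlap of changed groups. Across genes, which are not independent replicates, the fold changes correlated at 0.468, against 0.501 simulated with no effect, and their covariance was 0.0686 against 0.015 simulated. With a different control array for each comparison the correlation was 0.385 or 0.287 and the covariance 0.0599 or 0.0481. The correlation of siPsmd14 and siDdb1 was 0.573 (0.5 simulated, 0.432 or 0.316 with different control arrays) and their covariance 0.0569 against 0.0149 (0.0463 or 0.038 with different control arrays), with Csn3 as the 1 shared rise (1.94 and 1.83). That of siSox2 and siDdb1 was 0.369 (0.501 simulated, 0.32 or 0.124 with different control arrays) and the covariance 0.0424 against 0.015 (0.0378 or 0.0177 with different control arrays), with no gene called in the same direction and 2 called in opposite directions, Gfra1 (-1.11 and 1.66) and Irs4 (lower in siSox2 at -0.73). Part of the excess of shared calls over independent lists may come from the shared controls, whose share of the covariance is already in the simulated value. The count of 92 genes called in 1 direction was 1 without either siNonTarget array, 41 without siSox2 replicate 2 and 7 without siPsmd14 replicate 1.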

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

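The crossed replicate block was the 1 alternative chosen after the data were seen. Under the alternatives run, no correlation of fold changes changed sign, nor did any named gene, target or list that passed its threshold with or without the change. The share of higher calls in siPsmd14 against siSox2, 48.4%, was 50.5% with quantile normalization, 53.2% with only its 4 arrays and 35.6% to 54.2% with 1 array left out, and in siDdb1 against siSox2, 44.6%, it was 40.2% with array medians subtracted and 34.4% to 50.5% with 1 array left out. Of the values of genes under the naming rule, 2272 kept their side of the threshold, 98 lost it and 21 gained it under settings other than leaving out 1 array, with 51 of the losses where only the 4 arrays compared were fitted, and with 1 array left out these were 1699, 437 and 24. A group left with 1 array is assumed to vary like the other groups. Leaving out an array of a group outside a comparison does not change its fold changes and only leaves fewer arrays to estimate the spread. Of the list calls, 233 held and 133 were lost with all arrays, and 443 held and 45 were lost with 1 array left out. Of the 133 list calls lost with all arrays, 61 were lost with an estimated correlation and 56 with fry, the alternative list tests. Each other setting with all arrays lost 2 to 6. Where no cause is given below, the cause was not tested.

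The siDdb1 count of 12 went to 0 without the dimmer 50% of probe sets, 0 without probe sets of mean log2 under 5, 0 with only its 4 arrays in the fit and 0 at an adjusted p of 0.01. The siPsmd14 against siDdb1 count of 186 went to 121 without probe sets of mean log2 under 5, 122 with array weights, 11 with only its 4 arrays and 22 at an adjusted p of 0.01. At an adjusted p of 0.01 the other counts were 375 for siSox2, 86 for siPsmd14, 331 for siPsmd14 against siSox2 and 383 for siDdb1 against siSox2, by the stricter threshold itself. With a 2-fold minimum they were 762, 395, 681 and 737, and the overlap of siSox2 and siPsmd14 was 60. With only the 4 arrays compared, siPsmd14 against siSox2 gave 455 and siDdb1 against siSox2 789. The overlap of siPsmd14 and siDdb1 was 0 without the dimmer 50% of probe sets.

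The replicate numbers as given did not pair the arrays in a uniform way. The deviations of same-numbered arrays correlated at 0.242 and 0.0558 between siNonTarget and siSox2 or siPsmd14, -0.213 between siNonTarget and siDdb1, 0.0843 between siSox2 and siPsmd14, -0.217 between siSox2 and siDdb1, and 0.185 between siPsmd14 and siDdb1. With the replicate block the counts were 1256, 519 and 2 for siSox2, siPsmd14 and siDdb1 against siNonTarget, 1294 and 1389 for siPsmd14 and siDdb1 against siSox2, and 180 for siPsmd14 against siDdb1. The overlap of siPsmd14 and siDdb1 was 0 with the block. With the siDdb1 numbers crossed, siDdb1 gave 53 calls against siNonTarget and 1471 against siSox2, where the fit without a block gave 12 and 1387. An array effect that the siDdb1 numbers do not follow is not excluded.

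With an estimated correlation, 0 lists passed in siSox2, 0 in siPsmd14, 0 in siDdb1 and 0 in each of the 3 direct comparisons. With fry, 2 passed in siSox2, 0 in siPsmd14, 0 in siDdb1, 1 in siPsmd14 against siSox2, 2 in siDdb1 against siSox2 and 0 in siPsmd14 against siDdb1. With control replicate 2 for the first knockdown and 1 for the second, the correlations were 0.287 for siSox2 and siPsmd14, 0.124 for siSox2 and siDdb1, and 0.316 for siPsmd14 and siDdb1.

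With 1 array left out, counts ranged from 153 to 1440 in siSox2, 17 to 1295 in siPsmd14, 0 to 146 in siDdb1, 325 to 1543 in siPsmd14 against siSox2, 319 to 1486 in siDdb1 against siSox2 and 11 to 884 in siPsmd14 against siDdb1. Overlaps ranged from 1 to 125, 0 to 9 and 0 to 41 for siSox2 with siPsmd14, siSox2 with siDdb1 and siPsmd14 with siDdb1. Lists past the threshold ranged from 7 to 13, 13 to 17 and 7 to 10 against siNonTarget, and 8 to 11, 7 to 11 and 8 to 13 in the direct comparisons. Ddb1 in siDdb1 ranged from -2.18 to -1.12. Another probe set of each target gave no value, since each target has 1. Signal over background could not be assessed from the summarised values.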

Other observations

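The tests of other RNA on the siSox2 arrays and of low p53 signal on the control arrays were chosen only after the result was seen, and so were both tests of list calls without 1 array, while the spread asked of the array medians was added after their values were seen.

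The list of 20 measured cholesterol synthesis genes shifted up by camera in siSox2 (median 0.27, camera adjusted p = 0.00141, adjusted p = 0.617 with an estimated correlation) and down in siPsmd14 (median -0.32, with 20 of 20 below 0, camera adjusted p = 1.56e-05, adjusted p = 0.362 with an estimated correlation) and siDdb1 (median -0.20, with array medians of -0.351 and -0.035, camera adjusted p = 0.00114, adjusted p = 0.59 with an estimated correlation). No member passed in these 3 comparisons over all probe sets or adjusted over the list alone. In siPsmd14 against siSox2, Mvk (-0.79), Hmgcs1 (-0.60) and Mvd (-0.70) were lower, and 14 were adjusted over the list alone (camera adjusted p = 2.86e-11, adjusted p = 0.499 with an estimated correlation). In siDdb1 against siSox2, Srebf2 (-0.63) was lower and 13 were adjusted over the list alone (camera adjusted p = 8.62e-08, adjusted p = 0.723 with an estimated correlation), while in siPsmd14 against siDdb1 the list did not pass (median -0.075, camera adjusted p = 0.0536). The camera adjusted p was 0.128 in siSox2 without siNonTarget replicate 2, and in siDdb1 it was 0.209 without siNonTarget replicate 1 and 0.329 without siDdb1 replicate 1.

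Genes of the endoderm and matrix lists rose in siSox2, where the type IV collagens Col4a2 (3.28) and Col4a1 (2.70) and the endoderm gene Dab2 (2.67) rose while the laminin gene Lama1 fell. Of 24 primitive endoderm genes 6 rose and 1 fell, and 7 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.00141, adjusted p = 0.51 with an estimated correlation). Of 25 extracellular matrix genes 5 rose and 1 fell, and 14 rose and 2 fell adjusted over the list alone (camera adjusted p = 2.32e-07, adjusted p = 0.51 with an estimated correlation). In siPsmd14 Col4a2 (1.70) and Col4a1 (1.16) rose, and 9 matrix genes and 5 endoderm genes did adjusted over the list alone (camera adjusted p = 3.88e-07 and 0.00241, adjusted p = 0.31 with an estimated correlation for both). The matrix list also shifted up in siDdb1 (camera adjusted p = 0.00609, adjusted p = 0.582 with an estimated correlation, and 0.0576 without siNonTarget replicate 2). Of 8 measured 2-cell-like genes none passed over all probe sets, while 3 rose in siSox2 and 6 in siDdb1 adjusted over the list alone (medians 1.2 and 1.3, camera adjusted p = 0.00141 and 7.28e-05, adjusted p = 0.517 and 0.582 with an estimated correlation). Another 15 genes of the 2-cell-like list, among them its Zscan4 genes and Dux, were not measured, so the shift covers only part of it. The array medians of the list were uneven, at 0.401 and 1.835 in siSox2 and 1.897 and 0.635 in siDdb1. The camera adjusted p of that list was 0.0713 in siSox2 without siSox2 replicate 2, 0.00979 in siDdb1 without siDdb1 replicate 1, and 0.0712 in siPsmd14. Germline genes shifted up in siSox2 with Ddx4 (0.92, camera adjusted p = 0.00141), in siPsmd14 with Tex19.1 (1.29, camera adjusted p = 0.0107) and in siDdb1 (camera adjusted p = 0.0228), with an adjusted p of 0.51, 0.362 and 0.582 with an estimated correlation. The germline value was 0.082 in siSox2 without siSox2 replicate 2, and in siDdb1 it was 0.0846 without siNonTarget replicate 1 and 0.0799 without siDdb1 replicate 1.

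Signalling feedback targets shifted up in siDdb1 (camera adjusted p = 0.0228, adjusted p = 0.582 with an estimated correlation), with 3 of 26 higher adjusted over the list alone and Dusp4 at 1.02 (adjusted p = 0.172). The value was 0.0586 without siNonTarget replicate 1, 0.0642 without siDdb1 replicate 1 and 0.667 with all probe sets of the lists. In siSox2 Id2 rose (1.18) and Etv4 (-1.14) and Egr1 (-1.84) fell, in a list that did not pass (camera adjusted p = 0.957). Mesoderm genes shifted up in siPsmd14 (camera adjusted p = 0.048, adjusted p = 0.362 with an estimated correlation), with Lhx1 higher (0.93) and Bmp4 lower (-0.98). That value was 0.0922 without siNonTarget replicate 1, 0.0532 without siPsmd14 replicate 1, 0.16 without siPsmd14 replicate 2 and 0.241 without the dimmer 50% of probe sets. The stress regulator gene Cebpb rose in siSox2 (2.31) and siPsmd14 (1.25), the latter with Ddit3 (1.21), in a list of 33 that did not pass (camera adjusted p = 0.266 and 0.131, and 0.651 in siDdb1). The interferon list had camera adjusted p of 0.957, 0.0972 and 0.776 in siSox2, siPsmd14 and siDdb1, and the CUL4-DDB1 list 0.46, 0.619 and 0.988. Among heat shock chaperones Serpinh1 (1.72), Cryab (2.46), Hspa1b (1.01) and Bag3 (1.06) rose in siSox2, in a list that did not pass (camera adjusted p = 0.0899). P53 targets shifted up in siSox2 as well (median 0.28, camera adjusted p = 0.00141, adjusted p = 0.617 with an estimated correlation), with Cdkn1a past the threshold (1.24) and 9 of 35 higher and 1 lower adjusted over the list alone. The array medians of that list were 0.176 on siSox2 replicate 1 and 0.381 on replicate 2.

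The Sox2 signal differed little beside 1320 calls in siSox2. A candidate explanation is signal compression at the brightness of the Sox2 probe set. Of 614 probe sets within 0.5 log2 of the Sox2 control level, 2 were lower by over 1 log2 past the threshold in any comparison, Gsta4 and Ckb. The bounds were 0 for compression and 5 against it, but a low count may also mean that few bright genes responded, so it cannot decide. Just outside that window, Ddb1 (control mean 11.85, Sox2 12.35) read 9.67 and 10.73 in siDdb1. A large fall was thus readable near that brightness on 1 other probe set, though that change did not pass the threshold against siNonTarget. That arrays labelled siSox2 hold other RNA stays open too, since 1 of the 6 other arrays lay below the higher siSox2 array in Sox2 signal (12.07 against 12.1), although the other siSox2 array was the lowest of the 8 (11.84) and siSox2 had the lowest group mean (11.97, the next 12.24). Small interfering RNA can also lower protein more than transcript, which was not tested. Ckb was named after its value was seen.

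P53 targets shifted up by camera in siPsmd14 and siDdb1, where 6 and 0 of 35 were past the limma threshold over all probe sets, 19 and 20 rose adjusted over the list alone, and the list passed in neither with an estimated correlation (adjusted p = 0.31 and 0.487). Low signal on the control arrays as the whole cause is argued against by siSox2 as the reference, where 5 calls of p53 targets were higher in the 2 knockdowns together and none was lower, though the list gave 0.169 in siDdb1 against siSox2 without siDdb1 replicate 1. A single array carrying the shift in both knockdowns is argued against by the array medians, though not by the camera calls. The list passed by camera against siNonTarget without any 1 of the 8 arrays (highest adjusted p = 9.5e-10 in siPsmd14 and 8.82e-12 in siDdb1). Those calls used the preset correlation of 0.01, while the estimate for this list was 0.33, so they cannot decide. The 4 array medians of the knockdowns all lay above those of the control arrays (-0.111 and 0.111). They were 0.714 and 0.509 in siPsmd14 and 0.831 and 0.417 in siDdb1. A single carrier would leave the other arrays near the control arrays. The lowest of the 4 was 0.417, above the bound of 0.3 set against a single carrier. The margin of 0.117 was under the SD of 0.15 between arrays of a group. The median of siSox2 replicate 2 lay at 0.381. A response of p53 to loss of either gene stays a hypothesis.

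Proteasome subunit transcripts shifted up by camera in siPsmd14, where 0 of 40 were past the limma threshold over all probe sets, 13 rose and 1 fell adjusted over the list alone, and the list did not pass with an estimated correlation (adjusted p = 0.415). A shift of all bright genes is argued against, since the list median of 0.278 lay at percentile 100 among 10000 random lists matched on mean level, whose highest median was 0.11. A single array carrying the shift cannot be told apart, since the camera adjusted p was 0.0748 without siPsmd14 replicate 1. The lower siPsmd14 array lay at 0.114, above the highest other array (0.021), but above the bound of 0.1 by 0.0139 with an SD of 0.063. Feedback on proteasome genes after loss of a subunit is a candidate explanation that these tests leave open.

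A hypothesis that the array with less target signal shows the larger response held in 2 of 3 knockdowns, which cannot reach a p of 0.05. The trophectoderm median was 1.68 against 1.40 in siSox2 and the p53 median 0.831 against 0.417 in siDdb1, while the proteasome median in siPsmd14 was 0.114 on the array with less Psmd14 and 0.428 on the other.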
